A study of Homo sapiens with 4 samples.

How the data were processed

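Messenger RNA was sequenced from K562 cells, an established human line derived from chronic myeloid leukemia, grown in RPMI+dS or in HPLM+dS. RPMI is a standard culture medium, and HPLM (human plasma-like medium) is a medium composed to hold polar metabolites and salts near their levels in human plasma. The labels do not spell out dS, which was added to both media. Each medium had 2 libraries, which the series' design text calls biological replicates. Per the labels' protocols, cells that had been passaged in their medium were seeded at 200000 cells per mL in 6 cm dishes with 6 mL of medium and grown for 24 h. From 700 ng of total RNA, stranded mRNA libraries were made with an Illumina TruSeq kit, pooled and read as single-end reads of 40 bp.

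The deposited values are raw counts of reads per Ensembl gene, made by the authors with TopHat2 2.1.1 and featureCounts against GRCh37, per the submitters' processing notes. The version of featureCounts, the annotation release, the strand setting and any filter on reads are not given in the sources used here. Reads from overlapping genes on opposite strands can therefore not be told apart with certainty, and counts of near-identical copies (HBA1 and HBA2, HBG1 and HBG2, AKR1C1 and AKR1C2, GYPB and GYPE, HSPA1A and HSPA1B) are uncertain, since short reads can be split between them or dropped. Each library's table held 57773 gene rows and 0 columns that belonged to no sample. Gene symbols were looked up by Ensembl ID: 39538 IDs had a name in a gene name table and 12800 more in GENCODE release 29, while 5435 had none. Named IDs held 99.3% of the counts. GENCODE release 29 describes another genome build than the authors', so it was used only for names, transcript length, GC content and the order and strand of neighbouring genes, and no coordinates are given.

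Totals were 16674164 and 23493872 counts for replicates 1 and 2 in RPMI+dS, and 23334547 and 18477289 in HPLM+dS. Counting error is small beside the spread between replicates for genes with many counts and large for genes with about 10 or fewer. The replicates of each medium were compared by a chi-square test of their counts over genes with at least 20 counts in the pair. The statistic per degree of freedom was 6.80 in RPMI+dS and 5.96 in HPLM+dS, so both pairs differed by more than sampling noise and each library counted as 1 replicate. What made the replicates separate is not described further in the labels.

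Media were compared with edgeR 4.0.16 (R 4.3.3) on the counts as deposited. Genes were kept by filterByExpr with the medium as group (minimum count 10, minimum total count 15), libraries were scaled by TMM, with factors from 0.995 to 1.008, and the quasi-likelihood test was applied to the coefficient HPLM+dS minus RPMI+dS. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes were taken from the size of the change and its F statistic. Fold values are the fitted ratios from this model, and CPM values are counts scaled by TMM-adjusted library totals (cpm of edgeR), given as mean ± SD of 2 libraries. A comparison of single values between 2 and 2 libraries cannot give a two-sided exact permutation p under 0.333, so p-values come only from models that share the spread across genes.

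Before the data were examined, 45 gene lists with 846 members, the main tests and the alternatives were fixed. Of the members, 836 matched a gene ID. TXNIP and the few other unmatched members were not analysed here. The 43 lists with at least 4 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list and with fry. Beside each list stand the number of members called over all genes tested and the number called when p-values are adjusted over the list alone. The genes named in the text follow a rule fixed at the same time: the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM in the higher medium and no overlap between media, up to 4 called members of each called list and up to 2 of each other list, and 20 genes chosen in advance, of which 19 were tested. Some genes that the rule selects are not reported here. Genes named outside it are marked as chosen after their values were seen.

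The gene and list tests were first tested on simulated data with the real means and library sizes. In these data 200 genes were changed, and 15004 genes passed the filter. A changed gene that failed the filter counted as not called. Counts were drawn independently for each gene, with the spread typical of its expression level, so the shares in the real data may differ. Of the genes changed 1.25-fold, 20% were called. For 1.5-fold, 2-fold and 4-fold changes the shares were 52%, 72% and 94%. Of 128 calls, 9 were unchanged genes, and 0 genes were called when no change was simulated.

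Alternatives were RLE, upper quartile and total-count scaling, no count filter or a filter of at least 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out in turn, and an adjusted p under 0.01. With a library left out, the lone library of a medium is assumed to vary like the pair of the other medium. Figures were drawn with matplotlib.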

Results

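Gene expression was measured by mRNA sequencing in K562 cells, a leukemia line with erythroid and megakaryocyte features, passaged in RPMI+dS or HPLM+dS and then seeded in the same medium for 24 h (n = 2 libraries per medium). Libraries held 16674164 to 23493872 counts, and 25478 to 27250 genes had at least 1 count. Across the tested genes, the log2 CPM values of replicates correlated at 0.993 in RPMI+dS and 0.994 in HPLM+dS, against 0.984 to 0.987 between media. These correlations are across genes, which are not independent replicates. The first principal component held 64.3% of the variance and separated the media.

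The comparison asks which transcripts depend on the medium in which the cells are grown. In HPLM+dS, the embryonic globin gene HBE1 and the red cell anion exchanger gene SLC4A1 were higher, and PHGDH, for serine synthesis, and ASNS, for asparagine synthesis, were lower. Of 15316 genes tested, 770 were higher and 561 lower in HPLM+dS (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 309 were at least 2-fold higher and 108 at least 2-fold lower. All 1331 called genes had both libraries of one medium above both of the other, which held for 54.5% of tested genes against 33.3% by chance. Without RPMI+dS replicate 1 the counts were 416 higher and 283 lower, and the lower count was 362 without HPLM+dS replicate 1 and 342 without HPLM+dS replicate 2. DESeq2 called 184 genes at least 2-fold higher and 67 at least 2-fold lower, and without a count filter 900 genes were lower, 174 of them at least 2-fold.

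**Figure D1:**
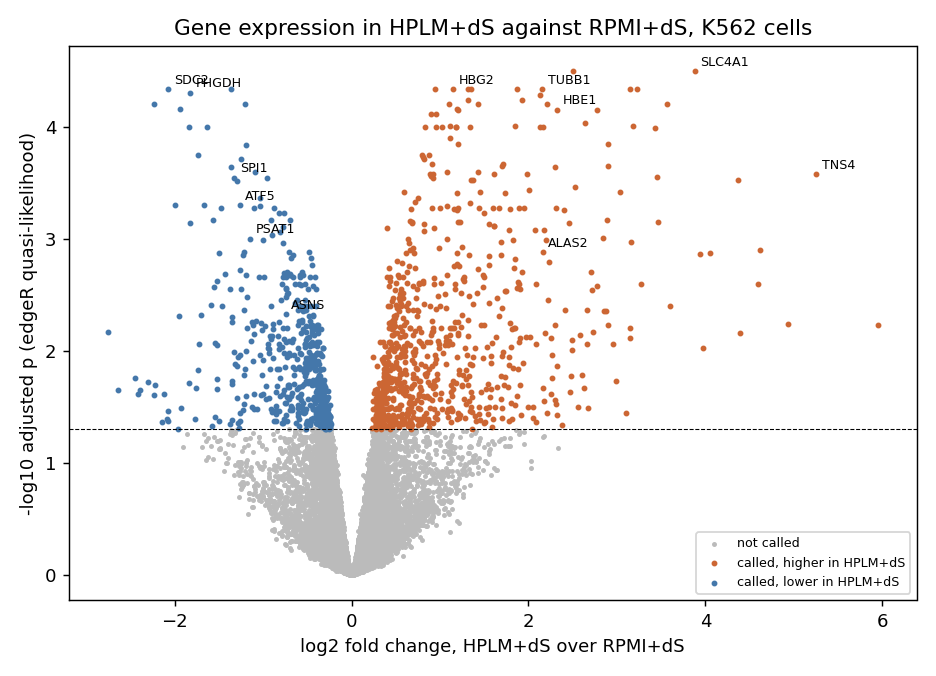
Each point is 1 of 15316 tested genes: the x axis gives the log2 fold change of HPLM+dS over RPMI+dS and the y axis the negative log10 of the adjusted p of edgeR's quasi-likelihood test, with the dashed line at 0.05. Among the labelled genes, SLC4A1, HBE1 and TNS4 lie on the right and PHGDH, SDC2 and SPI1 on the left.

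The largest rise among genes with at least 5 CPM in the higher medium was that of TNS4 (ENSG00000131746), which encodes the focal adhesion protein tensin 4. It went from 0.270 ± 0.041 to 10.8 ± 6.1 CPM (SD, n = 2 per medium), a log2 fold change of 5.25 ± 0.53 (SE, edgeR adjusted p = 2.6e-04), or 4.53 without HPLM+dS replicate 2. SLC4A1 (ENSG00000004939), the anion exchanger band 3 of the red cell membrane, rose 14.8-fold, from 2.33 ± 1.06 to 33.0 ± 0.41 CPM (edgeR adjusted p = 3.2e-05). TRBC2, a T cell receptor beta constant gene, rose 11.8-fold, VEPH1 9.40-fold, the long non-coding RNA LINC00520 8.83-fold, and PDGFB, the platelet-derived growth factor B chain, 8.20-fold. The log2 fold change of PDGFB, 3.04 with all libraries, was 3.74 without RPMI+dS replicate 2. Under the same limit of 5 CPM, the largest falls were those of FAM107B, at a log2 fold change of -2.23 ± 0.17, and of SDC2 (ENSG00000169439). SDC2, the cell-surface proteoglycan syndecan 2, fell from 23.5 ± 1.7 to 5.60 ± 0.14 CPM (edgeR adjusted p = 4.6e-05). PLXDC2 fell 4.0-fold, ANXA3 (annexin A3) 3.83-fold, PYCARD, the adaptor of the inflammasome, 3.58-fold, and PHGDH 3.54-fold.

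Of 9 globin genes tested, 8 rose in HPLM+dS and 0 fell over all genes tested, and 9 rose when adjusted over the list alone (camera adjusted p = 3.4e-22, or adjusted p = 0.668 with an estimated correlation). HBE1 (ENSG00000213931), the embryonic epsilon globin, rose 5.01-fold, from 299.8 ± 112 to 1499.5 ± 52 CPM (SD, n = 2 per medium; log2 fold change 2.33 ± 0.19, edgeR adjusted p = 7.1e-05). The fetal gamma globins HBG2 (ENSG00000196565) and HBG1 rose 2.21-fold and 1.94-fold, to 1416 ± 64 and 930 ± 39 CPM, with the division of reads between these near-identical copies uncertain. HBD, the minor adult delta globin, rose from 9.64 ± 2.58 to 22.9 ± 3.6 CPM. The exception over all genes was HBQ1, named after its values were seen, at a log2 fold change of 0.48 ± 0.15, or 0.31 without RPMI+dS replicate 2. The list's median log2 fold change was 1.27.

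Of 12 genes of heme synthesis, 4 rose and 1 fell (5 and 1 adjusted over the list alone), and the list's camera adjusted p was 4.8e-04, or adjusted p = 0.733 with an estimated correlation. ALAS2 (ENSG00000158578), which catalyses the first step of heme synthesis in erythroid cells, rose 4.47-fold, from 21.7 ± 12.7 to 94.5 ± 16.3 CPM (log2 fold change 2.16 ± 0.28, edgeR adjusted p = 0.0013). Its log2 fold change was 2.89 without RPMI+dS replicate 1. SLC25A37, the mitochondrial iron importer mitoferrin 1, rose 1.76-fold. FECH, which inserts the iron, rose 1.31-fold, a call that ended without RPMI+dS replicate 2 (edgeR adjusted p = 0.0748) and without HPLM+dS replicate 2 (0.0787). TMEM14C, named after its values were seen, was the member that fell, by 0.25 on the log2 scale, a call that ended whenever any of the 4 libraries was left out (edgeR adjusted p from 0.0620 to 0.203).

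Of 22 erythroid transcription factors and membrane proteins, 9 rose, 1 fell and 12 did not pass the test (12 rose and 3 fell adjusted over the list alone). The list's camera adjusted p was 5.3e-09, or adjusted p = 0.733 with an estimated correlation. LMO2, a transcription cofactor of early blood cells, rose 2.29-fold, from 77.5 ± 8.7 to 177 ± 13 CPM (edgeR adjusted p = 6.9e-05). EPB42, which encodes protein 4.2 of the red cell membrane skeleton, rose 4.92-fold. GYPE, of the glycophorin family and named after its values were seen, fell 1.68-fold, and GYPB, a near-identical relative, had a log2 fold change of -0.53 ± 0.21 that did not pass the test. It was called without RPMI+dS replicate 2 (-0.87, edgeR adjusted p = 6.1e-05), and without RPMI+dS replicate 1 it was at -0.14. The erythroid regulators GATA1 and KLF1, also named after their values were seen, did not pass it either, at 0.13 ± 0.07 and 0.32 ± 0.11. GATA1 was at 0.063 without HPLM+dS replicate 2. KLF1 was called without RPMI+dS replicate 1 (0.50, edgeR adjusted p = 0.0420) and without HPLM+dS replicate 2 (0.42, 0.0436), and was at 0.14 without RPMI+dS replicate 2 and 0.20 without HPLM+dS replicate 1.

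**Figure D2:**
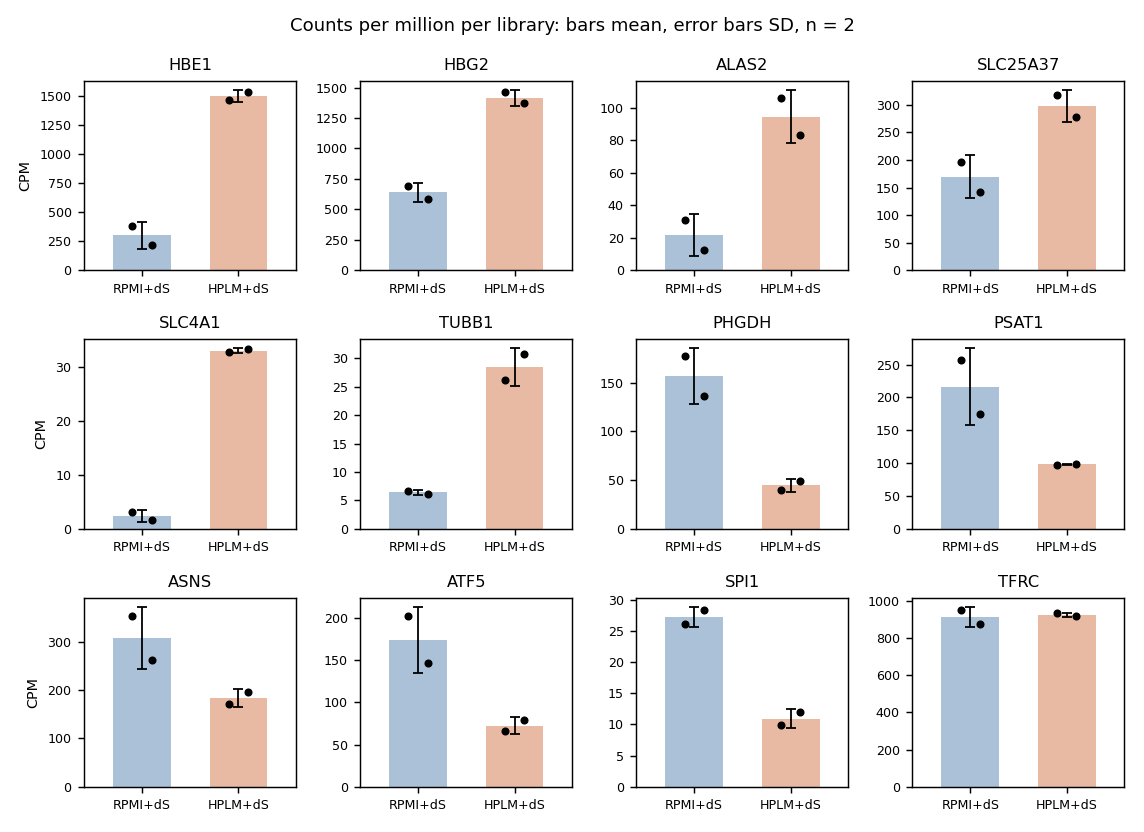
CPM of 12 genes in RPMI+dS and HPLM+dS, on axes that start at 0, with bars for means, error bars for SD and a point for each of 2 libraries per medium. HBE1 and SLC4A1 are higher in HPLM+dS and PHGDH and SPI1 lower, while TFRC is at 915 and 926 CPM.

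Of 15 megakaryocyte markers, only 6 were tested. Of these 6, 4 rose and 0 fell (4 and 1 adjusted over the list alone). The list's camera adjusted p was 4.5e-09, or adjusted p = 0.668 with an estimated correlation. TUBB1 (ENSG00000101162), the platelet beta-1 tubulin, rose 4.46-fold, from 6.4 ± 0.42 to 28.5 ± 3.3 CPM (log2 fold change 2.16 ± 0.14, edgeR adjusted p = 4.6e-05). THBS1 (thrombospondin 1) rose 10.8-fold from 0.412 ± 0.0999 CPM, and ITGB3, the beta 3 integrin of platelets, 4.70-fold from 0.789 ± 0.092 CPM. ITGA2B, its alpha IIb partner, rose by 0.84 ± 0.20 on the log2 scale. Without RPMI+dS replicate 1 its value was 0.54 (edgeR adjusted p = 0.119), without HPLM+dS replicate 2 the adjusted p was 0.0506, and DESeq2 gave 0.166.

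SPI1 (ENSG00000066336), the myeloid transcription factor PU.1, fell 2.5-fold, from 27.3 ± 1.6 to 10.9 ± 1.6 CPM (edgeR adjusted p = 2.8e-04). The surface markers CD33 and ITGAM also fell, at log2 fold changes of -0.74 ± 0.19 and -2.09 ± 0.55. For CD33 the call ended without RPMI+dS replicate 1 (edgeR adjusted p = 0.196) and without HPLM+dS replicate 2 (log2 fold change -0.47, adjusted p = 0.139). For ITGAM, at 1.14 ± 0.099 CPM in RPMI+dS, it ended without the same libraries (adjusted p = 0.160 and 0.154), and the log2 fold change was -1.38 without HPLM+dS replicate 2 and -4.24 without HPLM+dS replicate 1. DESeq2 gave ITGAM no adjusted p. Of 5 myeloid markers tested, 0 rose and 3 fell (0 and 4 adjusted over the list alone). The camera adjusted p was 2.1e-05, with a mean log2 fold change of -0.997 that became -0.16 without a count filter and -1.53 without HPLM+dS replicate 1. With an estimated correlation the adjusted p was 0.668.

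Markers of other cell types were few. Of the lymphoid markers only 3 were tested, too few for a list test. Among them CD3D rose from 13.6 ± 2.9 to 31.8 ± 1.4 CPM and CD3G from 0.339 ± 0.118 to 0.995 ± 0.113 CPM. The call of CD3G ended whenever any of the 4 libraries was left out (edgeR adjusted p from 0.0912 to 0.250). Of 5 fibroblast and epithelial markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.591). It was COL1A2, a collagen chain at 0.485 ± 0.082 and 1.68 ± 0.13 CPM, whose call ended with DESeq2 (adjusted p = 0.0619).

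Of 17 members of the serine, glycine and one-carbon list, 0 rose and 4 fell in HPLM+dS (1 and 5 adjusted over the list alone). The camera adjusted p was 2.8e-04, or adjusted p = 0.733 with an estimated correlation. PHGDH (ENSG00000092621), the first enzyme of serine synthesis from glucose, fell from 157 ± 29 to 44.3 ± 6.2 CPM (SD, n = 2 per medium; log2 fold change -1.82 ± 0.13, edgeR adjusted p = 5.0e-05). PSAT1 (ENSG00000135069) and PSPH, the next steps, fell 2.21-fold and 1.57-fold, and ALDH1L2, a mitochondrial folate enzyme, fell 2.82-fold. The call of PSPH ended without RPMI+dS replicate 1 (edgeR adjusted p = 0.0843). The list's median log2 fold change was -0.07 and its mean -0.31, or -0.14 without a count filter.

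Of 20 genes of the ATF4 pathway, the transcriptional arm of the integrated stress response, 0 rose and 6 fell (0 and 11 adjusted over the list alone). The camera adjusted p was 7.6e-09, or adjusted p = 0.733 with an estimated correlation. The transcription factor ATF5 (ENSG00000169136) fell 2.40-fold, from 174 ± 39 to 72.4 ± 9.8 CPM (edgeR adjusted p = 5.0e-04), and JDP2 fell 2.32-fold. ASNS (ENSG00000070669), asparagine synthetase, fell 1.68-fold, from 308 ± 64 to 184 ± 18 CPM (edgeR adjusted p = 0.0047). TRIB3, a pseudokinase induced by ATF4, fell 1.43-fold, a call that ended without RPMI+dS replicate 1 (edgeR adjusted p = 0.0604). CHAC1 and SLC7A11, other targets, had log2 fold changes of -0.26 ± 0.16 and -0.32 ± 0.14 that did not pass the test. CHAC1 was at -0.12 without HPLM+dS replicate 1 and -0.40 without HPLM+dS replicate 2. SLC7A11 was called with no count filter (edgeR adjusted p = 0.0232) and without RPMI+dS replicate 2 (-0.55, adjusted p = 5.1e-04), and was at -0.079 without RPMI+dS replicate 1. The list's median log2 fold change was -0.52, while its mean went from -0.51 to -0.32 without RPMI+dS replicate 1.

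Among cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, WARS1 fell 1.58-fold and YARS1 1.30-fold. Of 20 members, 0 rose and 2 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.0336, or adjusted p = 0.877 with an estimated correlation). The list's call ended without RPMI+dS replicate 1 (mean log2 fold change -0.05, adjusted p = 0.387), without HPLM+dS replicate 1 (0.0516) and with a filter at 1 CPM (0.0509). Without RPMI+dS replicate 2 its mean was -0.20, against -0.12 with all libraries. Without RPMI+dS replicate 1, the call of YARS1 ended (edgeR adjusted p = 0.0502) and WARS1 had a log2 fold change of -0.43, while DESeq2 gave WARS1 an adjusted p of 0.0543.

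Of 17 enzymes of alanine, aspartate, glutamate, proline and arginine metabolism, 0 rose and 3 fell (4 and 5 adjusted over the list alone): ASNS, the argininosuccinate synthase ASS1 and GPT2. The median log2 fold change was 0.04, while the mean was -0.18 and the camera test pointed down (adjusted p = 0.431). GPT2 (ENSG00000166123), the mitochondrial alanine transaminase, went from 20.5 ± 7.5 to 10.1 ± 0.30 CPM (log2 fold change -1.01 ± 0.22, edgeR adjusted p = 0.0165). Without RPMI+dS replicate 1 its log2 fold change was -0.60 (adjusted p = 0.0765), and the call of ASS1, at 3.65 ± 0.64 CPM in RPMI+dS, also ended (adjusted p = 0.0599). The list's mean was -0.09 without RPMI+dS replicate 1, and without RPMI+dS replicate 2 the list was called (mean -0.26, camera adjusted p = 0.00651). Amino acid transporters went both ways, with 3 of 19 higher and 3 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.804). The mean log2 fold change of the transporters was -0.03, or -0.17 without RPMI+dS replicate 2 and 0.13 without RPMI+dS replicate 1. SLC6A6, the taurine transporter, rose 1.55-fold and SLC7A8, a transporter of neutral amino acids, 1.89-fold.

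Of 13 mitochondrially encoded mRNAs, 5 rose in HPLM+dS and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 6.0e-04, or adjusted p = 0.668 with an estimated correlation). MT-ND5 rose 1.6-fold, from 643 ± 78 to 1030.1 ± 44 CPM (edgeR adjusted p = 7.1e-04), and MT-ND4 and MT-ND4L, both also complex I subunits, rose 1.32-fold each. MT-CO1 rose 1.19-fold, a call that ended without RPMI+dS replicate 1 (edgeR adjusted p = 0.0610). The other called member, named after its values were seen, was MT-CYB, at a log2 fold change of 0.24 ± 0.06. Its call ended without RPMI+dS replicate 2 (0.0955), HPLM+dS replicate 1 (0.0797) and HPLM+dS replicate 2 (0.0527). Mitochondrial mRNAs held 3.19% and 3.26% of counts in RPMI+dS and 3.78% and 3.81% in HPLM+dS. Mitochondrial rRNA held 0.458% to 0.468% in the 4 libraries. Nuclear complex I subunits had 1 of 34 members higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.748).

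Replication-dependent histone mRNAs mostly lack poly-A tails and so can track RNA selection as well as DNA synthesis. Whether the members tested here carry tails was not measured. Of 10 members, 1 rose and 0 fell (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.0139, or adjusted p = 0.877 with an estimated correlation. The member that rose was H2BC21, from 28.0 ± 3.1 to 46.1 ± 7.4 CPM, a call that ended without RPMI+dS replicate 1 (edgeR adjusted p = 0.0634). The call of the list ended without RPMI+dS replicate 1 (mean log2 fold change 0.21, adjusted p = 0.323) and without HPLM+dS replicate 1 (0.20, adjusted p = 0.161). The mean was 0.33 with all libraries and 0.16 without a count filter.

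Of 23 MYC targets and ribosome biogenesis genes, 0 rose and 4 fell (0 and 8 adjusted over the list alone): the nucleolar genes UTP20, WDR43, NOP2 and NOP58, by 1.21-fold to 1.27-fold. The list's median log2 fold change was -0.17 (camera adjusted p = 2.8e-04), and its mean went from -0.18 to -0.11 without RPMI+dS replicate 1 (adjusted p = 0.0442). With an estimated correlation its adjusted p was 0.877. The calls of UTP20 (edgeR adjusted p = 0.183 and 0.181) and NOP58 (0.218 and 0.172) ended without RPMI+dS replicate 1 and without HPLM+dS replicate 2. Those of WDR43 and NOP2 ended without these libraries (0.187 and 0.0947, and 0.15 and 0.116) and without HPLM+dS replicate 1 (0.143 and 0.157). MYC itself did not pass the test, at 282 ± 10 and 261 ± 15 CPM.

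Of 22 G1/S and DNA replication genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.0411). With an estimated correlation the adjusted p was 0.733. The member was PCNA, the replication clamp, 1.24-fold lower, whose call ended without RPMI+dS replicate 2 (edgeR adjusted p = 0.0953) and without HPLM+dS replicate 2 (0.137). The list's call ended without RPMI+dS replicate 1 (0.0533), without HPLM+dS replicate 1 (0.134) and with a filter at 1 CPM (0.0572). Of 10 polyamine genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.0457), and with an estimated correlation the adjusted p was 0.733. They were ODC1, the first enzyme of polyamine synthesis, and OAZ1 and OAZ2, antizymes that inhibit it. OAZ1 fell from 737 ± 18 to 552 ± 6.3 CPM, OAZ2 fell 1.39-fold and ODC1 1.28-fold, a call that ended without RPMI+dS replicate 1 (edgeR adjusted p = 0.128) and without HPLM+dS replicate 2 (0.0878). The polyamine list's call ended without RPMI+dS replicate 2 (0.0696), without HPLM+dS replicate 2 (0.157) and with a filter at 1 CPM (0.0587).

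**Figure D3:**
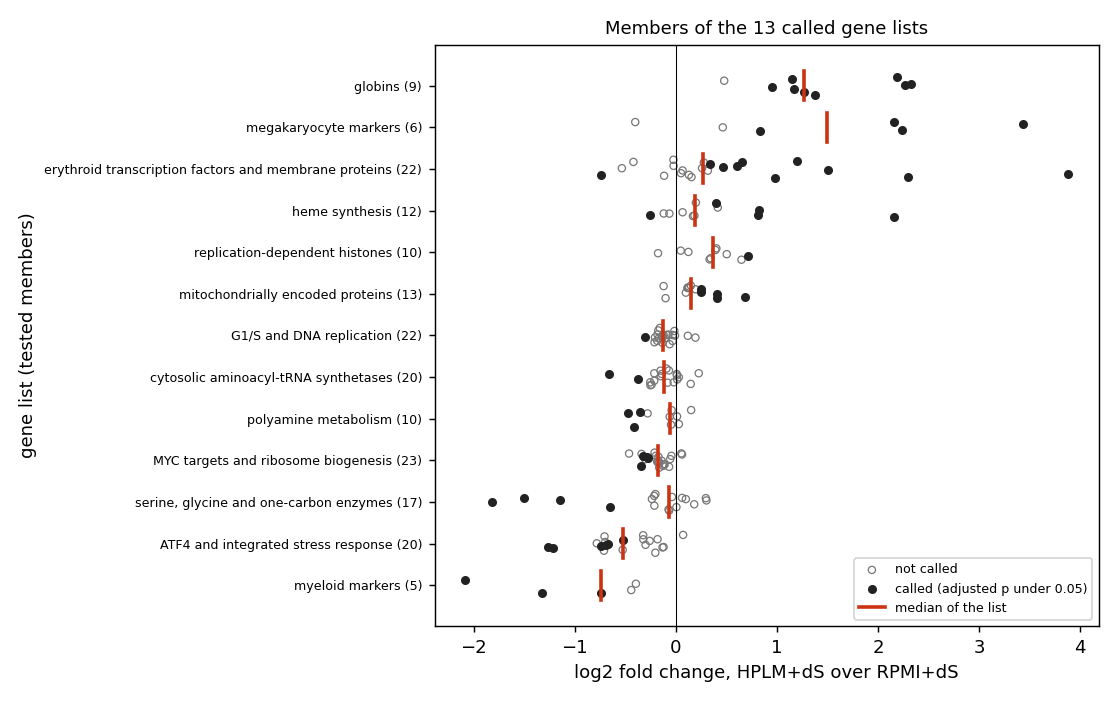
Log2 fold changes of HPLM+dS over RPMI+dS (x axis) for the tested members of the 13 called lists (y axis, with the number of members), 1 point per gene, filled where the gene was called, with the median as a red line. Globins lie to the right with a median of 1.27, and members of the ATF4 list to the left with a median of -0.52.

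The other lists were not called. Cholesterol synthesis and uptake had 0 of 25 members higher and 0 lower (also 0 and 0 adjusted over the list alone; camera adjusted p = 0.617), although without RPMI+dS replicate 2 the list was called (adjusted p = 4.5e-04). HMGCS1, a sterol-responsive member, had a log2 fold change of 0.10 ± 0.12. It was called without RPMI+dS replicate 2 (0.33, edgeR adjusted p = 0.0134) and had a negative value, not called, without RPMI+dS replicate 1 (-0.11). Fatty acid synthesis had 3 of 15 higher and 0 lower (4 and 1 adjusted over the list alone; adjusted p = 0.613, median -0.05 and mean 0.04). Among them FASN, fatty acid synthase, rose from 657 ± 14 to 881 ± 0.45 CPM. ACSL4 rose 1.32-fold, a call that ended without RPMI+dS replicate 1 (edgeR adjusted p = 0.0985) and without HPLM+dS replicate 1 (0.136). SCD, a desaturase of the same list, was at 386 ± 22 and 373 ± 14 CPM and did not pass the test. Fatty acid oxidation and PPAR targets had 0 of 16 higher and 3 lower (0 and 4 adjusted over the list alone). They included ACSL1, which fell 1.48-fold, and CPT1A, which fell 1.44-fold with a call that ended without HPLM+dS replicate 1 (edgeR adjusted p = 0.0929). That list stood just above the threshold (camera adjusted p = 0.0501), and was called with RLE (0.0499) or upper quartile scaling (0.0491), with no count filter (0.0263, with the test down but a mean log2 fold change of 0.0016 against -0.14 in the main fit), without RPMI+dS replicate 1 (0.0104) and without HPLM+dS replicate 2 (0.0232).

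Purine synthesis had 0 of 18 members higher and 0 lower and pyrimidine synthesis 0 of 18 and 0 (both 0 and 0 adjusted over the list alone; camera adjusted p = 0.652 and 0.443). The pyrimidine enzymes CAD and UMPS had log2 fold changes of 0.30 ± 0.09 (edgeR adjusted p = 0.0540) and -0.10 ± 0.09 (0.561; -0.003 without RPMI+dS replicate 1 and -0.21 without RPMI+dS replicate 2). CAD was called with total-count scaling (0.0474), no count filter (0.0033), limma voom (0.0460) and DESeq2 (0.0343). It was also called without RPMI+dS replicate 1 (0.0391) and without HPLM+dS replicate 2 (0.0457), and had a log2 fold change of 0.19 without RPMI+dS replicate 2. Glycolysis had 2 of 23 higher and 1 lower (5 and 4 adjusted over the list alone; adjusted p = 0.748), with ALDOC 1.62-fold higher and PKM 1.26-fold lower, the latter not called without RPMI+dS replicate 2 (edgeR adjusted p = 0.0569) or HPLM+dS replicate 1 (0.0807). The TCA list had 3 of 28 higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.892, median 0.001 and mean -0.003). IDH1 fell 1.47-fold and OGDH rose 1.32-fold, not called without RPMI+dS replicate 2 (edgeR adjusted p = 0.0556). The pentose phosphate pathway had 0 of 7 in either direction (0 and 1 adjusted over the list alone; adjusted p = 0.434) and branched-chain amino acid catabolism 0 of 18 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.748, median 0.05 and mean -0.02). That member was BCAT1, not called without RPMI+dS replicate 1 (edgeR adjusted p = 0.142), HPLM+dS replicate 1 (0.0991) or HPLM+dS replicate 2 (0.0557).

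Methionine, transsulfuration and glutathione genes had 1 of 17 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.480). MPST rose 1.29-fold, not called without RPMI+dS replicate 2 (edgeR adjusted p = 0.120), HPLM+dS replicate 1 (0.0832) or HPLM+dS replicate 2 (0.0718). CTH, which makes cysteine, fell 1.59-fold, with a log2 fold change of -0.38 without RPMI+dS replicate 1 (0.184) and no call without HPLM+dS replicate 1 (0.0991). MAT2A was at 735 ± 18 and 728 ± 77 CPM. NRF2 targets had 2 of 20 higher and 2 lower (2 and 4 adjusted over the list alone; adjusted p = 0.434). The camera test and the median, -0.07, pointed down, while the mean was 0.01, or -0.070 without RPMI+dS replicate 1, -0.035 without HPLM+dS replicate 1 and 0.158 without RPMI+dS replicate 2. NQO1 fell from 159 ± 22 to 90.5 ± 0.95 CPM and AKR1C1, a near-identical relative of AKR1C2, rose 1.56-fold. Iron handling had 0 of 11 in either direction (also 0 and 0 adjusted over the list alone; adjusted p = 0.875, median 0.02 and mean 0.002), and metallothioneins and zinc transport 0 of 5 (0 and 0 adjusted over the list alone; adjusted p = 0.574), with MT2A at 0.922 ± 0.024 and 1.65 ± 0.044 CPM.

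The unfolded protein response had 0 of 19 members in either direction (1 and 2 adjusted over the list alone; camera adjusted p = 0.574). Heat shock proteins had 0 of 16 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.0635), and this list was called with no count filter (0.00274), without RPMI+dS replicate 2 (5.6e-08) and without HPLM+dS replicate 1 (7.2e-06). The member was HSPB1, not called without RPMI+dS replicate 1 (edgeR adjusted p = 0.195) or HPLM+dS replicate 2 (0.137). Hypoxia targets had 1 of 18 higher and 1 lower (2 and 2 adjusted over the list alone; adjusted p = 0.922), namely ALDOC and BNIP3L, the latter 1.49-fold lower. Targets of p53 had 1 of 14 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.628). They were BTG2, not called with DESeq2 (adjusted p = 0.0518) or in 3 of the 4 fits that left out a library (edgeR adjusted p from 0.093 to 0.267), and TNFRSF10B, not called without HPLM+dS replicate 1 (0.0518).

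Signalling and immune lists went both ways or had few called members. Immediate-early genes had 1 of 16 higher and 2 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.330), with JUN 1.98-fold lower and IER5 1.29-fold lower, the latter not called without RPMI+dS replicate 1 (edgeR adjusted p = 0.0940) or HPLM+dS replicate 1 (0.0893). ERK feedback genes had 0 of 11 in either direction (2 and 2 adjusted over the list alone; adjusted p = 0.628). STAT5 and BCR-ABL output had 2 of 12 higher and 2 lower (3 and 5 adjusted over the list alone; adjusted p = 0.804, median 0.003 and mean -0.01), with SOCS1 2.18-fold lower and ID1 1.42-fold higher. Interferon-stimulated genes had 2 of 17 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.804). STAT2 rose 1.35-fold, not called without RPMI+dS replicate 1 (edgeR adjusted p = 0.0801) or HPLM+dS replicate 1 (0.0518). NF-kB targets had 0 of 9 in either direction (1 and 1 adjusted over the list alone; adjusted p = 0.650).

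Lysosome and autophagy genes had 3 of 24 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0847), a list called with no count filter (0.0435) and without RPMI+dS replicate 2 (0.0204). NEU1, a lysosomal sialidase, rose 1.48-fold. FOXO targets had 1 of 15 higher and 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.434), namely KLHL24, which rose 1.76-fold. G2/M and mitosis had 1 of 24 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.299), namely BUB1, not called without RPMI+dS replicate 1 (edgeR adjusted p = 0.0839) or HPLM+dS replicate 1 (0.112). Cytosolic ribosomal proteins had 1 of 58 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.0623, with the test and the median of -0.07 down). This list was called with no count filter (0.0144) and without HPLM+dS replicate 1 (0.0439). The member was RPL3, not called without RPMI+dS replicate 1 (edgeR adjusted p = 0.0706) or HPLM+dS replicate 2 (0.116). Of 3 MondoA-type glucose-responsive genes tested, ARRDC4, KLF10 and ARRDC3 had log2 fold changes of 0.14 ± 0.16, -0.26 ± 0.15 and -0.36 ± 0.11, none of which passed the test. TFRC, the transferrin receptor, was at 915 ± 55 and 926 ± 11 CPM.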

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

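With 2 libraries per medium, precision was limited by replicate number and, for genes with few counts, by depth. The counts of called genes in both directions stayed within 1.5 times under RLE, upper quartile and total-count scaling, limma voom and the filter at 1 CPM. With no count filter 900 genes were lower, 174 of them at least 2-fold, over more genes tested, and the cause was not tested further. DESeq2 called 184 genes at least 2-fold higher and 67 at least 2-fold lower. It gave no adjusted p to 2079 of 15316 genes, which therefore could not be called. How much of the difference this made was not tested. At an adjusted p under 0.01 the counts were 343 higher and 183 lower, with 194 and 56 at least 2-fold, as a stricter threshold must give fewer. Leaving out 1 library at a time, and so testing fewer samples, gave 416 to 795 higher, 283 to 642 lower, 214 to 298 at least 2-fold higher and 75 to 111 at least 2-fold lower. Of 86 called named genes, 52 were called in all 4 of these fits, as were 9 of the 13 called lists.

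Of the 13 called lists, 0 were called with an estimated correlation and 0 by fry's directional test. Both rest on few residual degrees of freedom, which limits how small their p-values can be. The estimated correlation was below the preset 0.01 for the myeloid (-0.085), mitochondrial (-0.078), polyamine (-0.042) and G1/S (0.0076) lists. A higher correlation therefore did not end those calls. It was above 0.01 for the other called lists, up to 0.81 for globins, where the cause was not tested. Of the named genes, 4 turned direction when a library was left out, and none was called in the fit where it turned. MAT2A had log2 fold changes from -0.126 to 0.0892 over these fits, HMGCS1 from -0.108 to 0.333, SCD from -0.11 to 0.0084 and TFRC from -0.046 to 0.0749. The cause was not tested.

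The labels give both media the replicate numbers 1 and 2 without saying what a number shares, and the deviations of same-numbered libraries correlated at 0.151 across genes. The second principal component, with 20.7% of the variance, parted replicates 1 from replicates 2 in both media. Once the first component separates the media, 4 libraries can part this way by chance. The parting therefore cannot decide whether a number shares something. With the replicate number as a block, 1718 genes were higher and 1542 lower, with 165 at least 2-fold lower. That fit leaves fewer residual degrees of freedom than the main fit, and its added calls rest on a pairing that the labels do not state. All 1331 genes called without the block were called in the same direction with it. The polyamine list was not called (adjusted p = 0.0540), while the lists of fatty acid oxidation (0.0421) and heat shock proteins (0.00156) were, as were the genes CAD and SLC7A11.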

Other observations

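The genes in this and the next paragraph lie beyond the lists and were chosen after their values were seen, and no theme was tested. WAS, a regulator of actin in blood cells, fell from 52.5 ± 0.77 to 22 ± 3.8 CPM (SD, n = 2 per medium; edgeR adjusted p = 1.9e-04), and CORO1A, a leukocyte actin-binding protein, fell from 11.6 ± 0.36 to 3.46 ± 0.028 CPM. AIF1 and EVI2B fell 3.01-fold and 2.5-fold from 5.03 ± 0.97 and 4.0 ± 1.22 CPM, the call of EVI2B ending without RPMI+dS replicate 2 (edgeR adjusted p = 0.0643). Not all leukocyte genes fell: MS4A2, MS4A3, MS4A4A and MS4A6A were called higher, at log2 fold changes of 2.78, 1.67, 1.61 and 1.13. These 4 lie next to each other among the tested genes, so they are not separate examples. Fits that leave out a library were not examined for them. HEMGN, an erythroid nuclear protein, rose from 157 ± 37 to 360 ± 40 CPM. CA1, a red cell carbonic anhydrase, rose 4.75-fold (log2 fold change 2.25, or 3.60 without RPMI+dS replicate 1 and 1.43 without RPMI+dS replicate 2). GFI1B, a repressor active in erythroid cells and megakaryocytes, rose 1.53-fold.

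HEY1, a Notch target, rose from 24.4 ± 6.7 to 94.1 ± 3.6 CPM (edgeR adjusted p = 5.9e-05), and ID3 rose 3.60-fold. RAB27B, a GTPase of secretory vesicles, rose from 15.6 ± 4.0 to 90.1 ± 8.5 CPM, and EPHB6, a receptor of the ephrin family, rose 4.50-fold. SAMD9 and GBP5, both known as interferon-inducible, rose 4.36-fold and 10.9-fold, GBP5 from 0.261 ± 0.113 CPM, although the list of interferon-stimulated genes was not called.

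Tests of library scaling, of red-cell RNA, of RNA without poly-A tails and of a single change in mitochondrial share were chosen only after the results were seen. The first pattern is the rise of globin, heme, erythroid and megakaryocyte genes with the fall of the myeloid list. Of the 15 markers of that list, only 5 were tested, and of the 15 megakaryocyte markers only 6. Correcting for GC content or transcript length left at least 97.6% of the median absolute log2 fold change of the 30 called members. A wrong scaling factor cancels within a library. The mean log2 count of the 4 higher lists minus that of myeloid markers was 2.42 and 2.08 in RPMI+dS. It was 3.84 and 4.45 in HPLM+dS, a difference of 1.89 ± 0.347 (SE over libraries). The lists were picked by their direction in these same libraries, so the sign was set in advance and the SE is no test. Still, no scaling factor can produce such a contrast. HBB, the abundant globin of adult red cells, rose by only 0.0823% of the 1200 CPM by which HBE1 rose. These values argue against such biases, against scaling and against adult red-cell RNA as the whole cause. The medium may favour erythroid and megakaryocyte transcription in each cell or a larger share of cells that express it, which bulk libraries cannot separate, and a difference in culture history or library handling that the labels do not record stays open as well.

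The second pattern is the rise of mitochondrial mRNAs. A change in the share of mitochondrial RNA that is alike for every gene is argued against, since the fold changes of the 13 mRNAs differed by more than their standard errors (heterogeneity Q of 8.8 per degree of freedom; log2 fold changes from -0.121 to 0.681). More carryover of RNA without poly-A tails into the HPLM+dS libraries cannot be told apart from a change in the cells. The 50 small non-coding RNAs tested had a median log2 fold change of -0.0643, with a bootstrap interval from -0.19 to 0.141, just below the median of 0.149 of the mitochondrial mRNAs. The histone list, from a class whose mRNAs mostly lack tails, had a median of 0.37. Whether its 10 tested members carry tails was not measured, so this list cannot decide the question, and carryover stays open. MT-RNR1 and MT-RNR2, at -0.17 ± 0.07 and -0.004 ± 0.05, did not rise with the mRNAs.

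The third pattern is that called genes lay next to each other. Of 14825 adjacent pairs of tested genes, 136 were called in the same direction, against a mean of 58.0 and a highest count of 90 in 10000 random placements among genes of similar expression (permutation p = 1e-04, the smallest these placements can give). Shared reads are argued against as the whole cause by the 95 pairs left without neighbours that overlap or share the first 3 letters of their names (random highest 71). Since this leaves in globin pairs such as HBB and HBD, the first 2 letters were also used, which left 93 pairs (random highest 70). A whole-chromosome copy-number difference is argued against by chromosome medians within 0.0384 of 0. Transcription running on into the next gene is argued against as the whole cause by 24 divergent pairs called together (random mean 10.2, random highest 24; permutation p = 2e-04). Regulation shared within chromosomal neighbourhoods and copy-number changes of single segments were not tested.

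Only 3 splits of the 4 libraries into 2 and 2 exist, too few for a share under 0.05. The split by medium, the 1 split with a count as large, called 1331 genes, and the highest of the others called 0. Each other split puts 1 library of each medium on either side. The difference between media then adds to the spread within groups, so this 0 is not a rate of false calls.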
